A study of Mus musculus with 39 samples.

How the data were processed

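RRBS and oxRRBS libraries were made from MspI-digested genomic DNA with a kit for the oxidation step, per the labels' protocols. The 39 libraries fall into 10 groups by assay, cell state or tissue, and genotype, as their titles give them. Reads were processed with Trim Galore, BSMAP and methylKit on genome build mm9, per the submitters' processing notes. The roles of the tools, their versions, the filters on coverage and the way libraries were combined are not given in the sources used here.

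The table of single CpGs holds total methylation as whole percent values deposited by the authors, with 330387 CpGs and 1 column per genotype and state. These columns were taken as the pooled RRBS groups. A further 4 columns per CpG have a suffix that the sources used here do not define and enter no comparison. The tile table holds fractions deposited by the authors for 377684 tiles of 200 bp, per the file headers for 5mC plus 5hmC and for 5mC, with the difference between genotypes and its q-value. The fractions were multiplied to percent. The tile table has 2 sets of these columns with headings that name no cell state, so neither set was given a state, and only tiles with values in a set enter it. The q-value columns hold -1 where the deposited difference is 0, and those tiles were taken as having no q-value. Another 4 columns of values, whose headings name neither a tissue nor a sample, were not used, and the liver libraries were therefore not analysed here.

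Neither table gives counts, coverage or values per library. Depth is therefore unknown, and no confidence interval or floor is given for methylation levels. The analysis planned before the data were examined was a quasi-binomial model of read counts per site with a coverage minimum, or limma on percent values per library. It also included permutation tests of library means and of the distance between libraries, and the coverage of the sex chromosomes. None of these was run, since each needs values of single libraries. In their place, means over CpGs or tiles were computed from the pooled values, each CpG or tile counting once, with p53-null minus WT or RA-treated minus naive as the direction. Differences of at least 10, 25 and 50 percentage points were counted, and means were taken per chromosome with at least 1000 CpGs, which were 20. Calls were tiles with q under 0.05 and a difference of at least 10 points in the authors' deposited table. Replicate numbers of the labels are titles only and do not enter any value.

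Methylation classes (limits 5, 20, 40, 60 and 80%) were formed from the mean of both genotypes in the other state or the other set, so that no value defines its own class. The number of measured CpGs per 200 bp tile served as a measure of local CpG density. Windows of 1000000 bp were kept with at least 20 tiles. Tiles of the CpG table were matched to the tile table by position, and 95601 tiles had CpGs and values in both sets. The deposited differences equalled the difference of the deposited levels within 0.0005 points.

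Named sites follow the rule set before the data were examined, as far as the tables allow. For tiles these were the 10 called tiles of largest increase and the 10 of largest decrease, 1 per 1000 bp. For CpGs they were the 10 largest changes each way of at least 25 points, 1 per 1000 bp. Ties were taken in order of chromosome name and position. The part of the rule that asks for libraries of both groups not to overlap could not be applied. Sites are given by mm9 position. The gene reference at hand is on GRCm38.p6, another build, so no gene or feature was assigned, and the gene lists fixed beforehand were not used. Coordinates count from 1.

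Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The counting of called tiles was tested on simulated data for the first set, total methylation: among 246422 simulated tiles with 200 changed, 200 were recovered. The simulated differences and q-values were fixed and had no noise. The outcome therefore checks only the counting rule, not how many true changes would be detected. Alternatives were autosomes only, a stricter call of 25 points and q under 0.01, any size of difference, tiles present in both sets, each tile counting once, CpGs above 0 in any total column, and tiles over 20% in the other set.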

Results

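DNA methylation was profiled in mouse embryonic stem cells (mESC) and liver that were either wild type (WT) or lacked p53, a transcription factor that responds to DNA damage and other stress. The series has 39 libraries in 10 groups, 33 from mESC and 6 from liver. The mESC were derived from embryos at day 2.5 and were grown either in 2i and LIF, inhibitors and a cytokine that hold them in the naive state, or with 1 uM retinoic acid (RA) for 4 days to induce differentiation. Reduced representation bisulfite sequencing (RRBS) samples CpG-rich MspI fragments and reads 5-methylcytosine (5mC) and 5-hydroxymethylcytosine (5hmC) together, here called total methylation. The oxidative form (oxRRBS) first converts 5hmC, so that only 5mC is read. Naive cells gave 5 WT and 3 p53-null libraries with each assay. RA-treated cells gave 5 WT and 4 p53-null RRBS libraries, and 4 WT and 4 p53-null oxRRBS libraries. Liver, taken at 16 weeks, gave 3 WT and 3 p53-null RRBS libraries and was not analysed here.

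The values were pooled by the authors into 1 column per group, for 330387 single CpGs and, in another table, for 200 bp tiles. Read depth is unknown and no value per library was used, so the group values below carry no SD and no n, and whether a difference exceeds the spread between libraries was not tested. The spread given instead is that over chromosomes, which describes the genome of the pooled groups and not their libraries. The only significance values are the q-values of the authors' deposited table and, under the other observations, a Fisher's exact test over pooled CpGs.

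The series concerns the role of p53 in DNA methylation of naive cells, so the genotypes were first compared there. In the naive state, mean total methylation over the 330387 CpGs was 9.77% in WT and 12.6% in p53-null cells, a difference of 2.82 percentage points. The p53-null value was the higher on 20 of 20 chromosomes with at least 1000 CpGs, by 2.47 to 3.38 points. CpGs at or above 80% made up 0.525% of the total in WT and 2.11% in p53-null cells, and those between 20% and 80% made up 18.1% and 19.5%. Most CpGs were unmethylated in either genotype, with 57.8% of them listed at 0 in WT and 58.7% in p53-null cells. At 46356 CpGs p53-null cells were higher by at least 10 points, and at 6214 they were lower by as much. At 25 points or more the counts were 12375 higher and 633 lower, and at 50 points or more 416 and 12. With each 200 bp tile counting once in place of each CpG, a choice made after seeing the data, the naive difference was 5.98 points.

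The naive difference was larger at CpGs with more methylation in RA-treated cells, up to the class from 60% to 80%. The classes use the level that the same CpGs had in the RA columns, which do not enter the naive comparison. Among the 29409 CpGs at 40% to 60% in RA-treated cells, naive WT cells averaged 30.0% and naive p53-null cells 41.1%, a difference of 11.1 points. For the 31297 CpGs at 60% to 80% the means were 47.6% and 59.4%, and for the 6219 CpGs above 80% they were 63.6% and 74.4%, a difference of 10.8 points. At the 19920 CpGs between 20% and 40% the difference was 6.34 points, and at the 20040 CpGs between 5% and 20% it was 1.59 points. CpGs under 5% in RA-treated cells numbered 223502 and differed by 0.0501 points. Among classes by the number of measured CpGs per tile, tiles with a single CpG held the largest difference. It was 8.96 points over 63543 CpGs, from 30.6% in WT to 39.5% in p53-null cells. In tiles with 9 or more measured CpGs, the CpG-dense sequence that is mostly unmethylated, the WT mean was 0.389% and the difference 0.0114 points over 90638 CpGs.

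The 10 named CpGs of largest naive increase were higher in p53-null cells by 70 to 81 points. They lay on 9 chromosomes. The first was on chromosome 9 (mm9 20039957 to 20039958), at 13% in WT and 94% in p53-null cells. Others were on chromosome 17 (16433384 to 16433385), from 16% to 90%, on chromosome 13 (64188508 to 64188509), from 21% to 93%, and on chromosome 7 (7478701 to 7478702), from 20% to 91%. The 10 of largest decrease were lower by 51 to 70 points. They included CpGs on chromosome 11 at 90416874 to 90416875, 79% in WT and 9% in p53-null cells, at 88327784 to 88327785, 69% and 8%, and at 94086627 to 94086628, 76% and 24%. Of these 10, 4 lay on chromosome 11. Another CpG, on chromosome 4 (151411354 to 151411355), was at 83% in WT and 20% in p53-null cells.

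**Figure D1:**
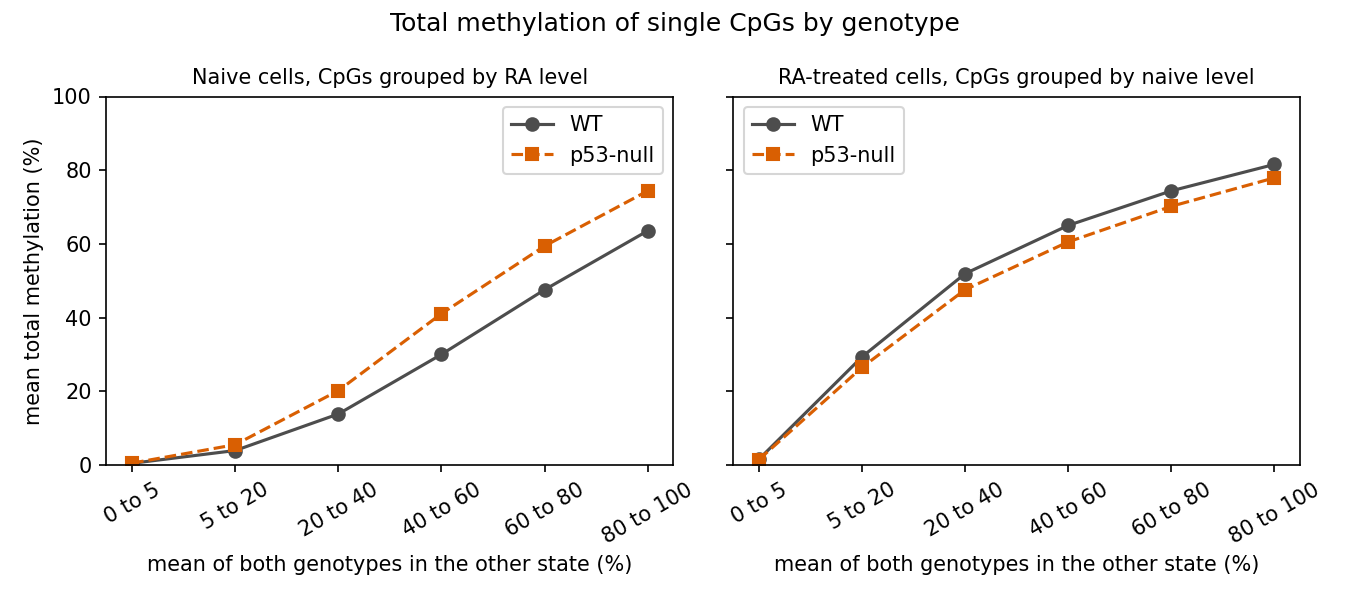
Mean total methylation (percent, vertical axis) of single CpGs in WT (circles) and p53-null (squares) cells, naive on the left and RA-treated on the right. CpGs are grouped by their mean level in the other state (horizontal axis), and the p53-null line lies above WT on the left, 41.1% against 30.0% in the class from 40% to 60%, and below it on the right, 60.6% against 65.0%.

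In RA-treated cells the order of the genotypes in mean total methylation was the opposite. Mean total methylation was 16.3% in WT and 15.1% in p53-null cells, a difference of -1.17 points, with p53-null cells the lower on 20 of 20 chromosomes (-1.46 to -0.776 points). CpGs at or above 80% made up 3.32% of the total in WT and 1.95% in p53-null cells. Those between 20% and 80% made up 23.1% and 23.8%, so this share was the higher in p53-null cells in both states. CpGs listed at 0 were fewer in p53-null cells here, 51.9% against 55.2% in WT. At 10 points or more, 11398 CpGs were higher and 30052 lower in p53-null cells, and at 25 points or more 930 were higher and 3812 lower. Grouped by their level in naive cells, the 25576 CpGs between 40% and 60% averaged 65.0% in WT and 60.6% in p53-null cells, and the 238231 CpGs under 5% differed by -0.0905 points. In tiles with a single measured CpG the means were 47.8% and 44.5%. With each tile counting once the difference was -2.33 points.

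Named CpGs lower in RA-treated p53-null cells included chromosome 16 (89964808 to 89964809), at 100% in WT and 15% in p53-null cells, and chromosome 6 (118752238 to 118752239), at 84% and 20%. Of the 10 of largest decrease, 4 lay within chromosome 11, from 87633718 to 89508769. Among those, the CpG at 88289730 to 88289731 was at 79% in WT and 9% in p53-null cells, and that at 89508768 to 89508769 was at 63% and 0%. The largest increase was on chromosome 8 (110533593 to 110533594), from 42% in WT to 100% in p53-null cells, followed by chromosome 13 (46894295 to 46894296), from 31% to 87%.

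**Figure D2:**
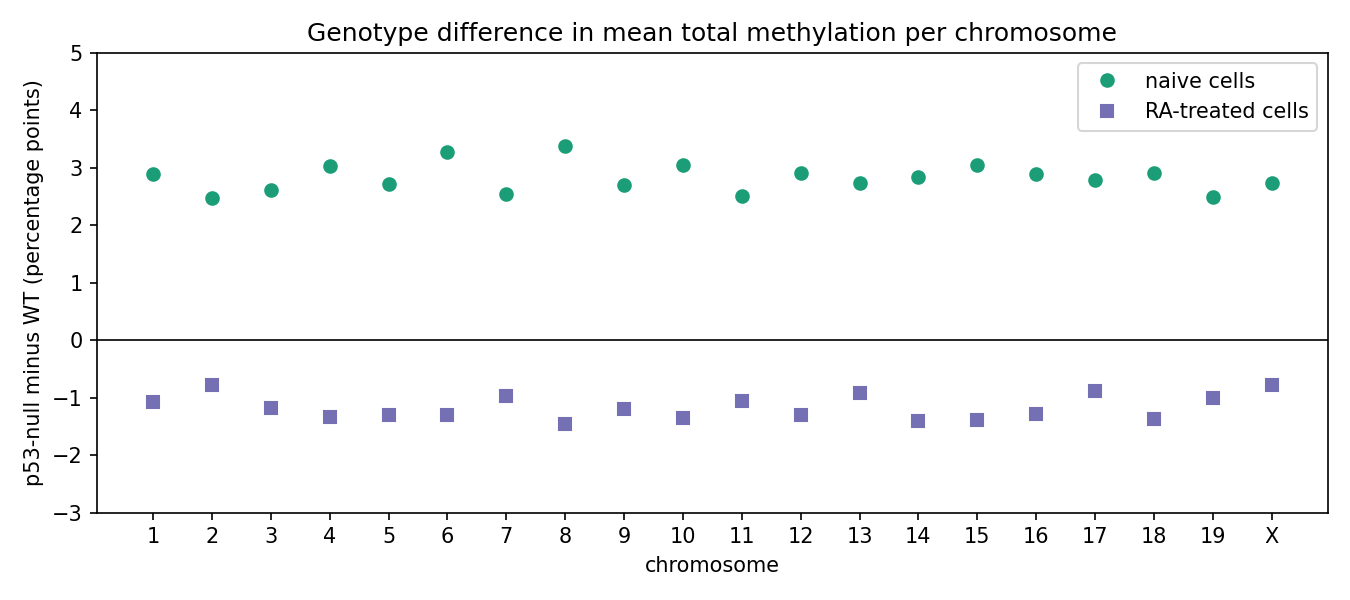
Difference in mean total methylation between p53-null and WT cells (percentage points, vertical axis) on each of 20 chromosomes (horizontal axis), for naive (circles) and RA-treated (squares) cells. The naive points lie between 2.47 and 3.38 and the RA points between -1.46 and -0.776, with the line at 0 between them.

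The states were next compared within each genotype. In WT cells mean total methylation was 9.77% in the naive and 16.3% in the RA-treated state, 6.48 points apart, with all 20 chromosomes higher after RA (5.10 to 7.20 points). At 25 points or more, 38610 CpGs were higher after RA and 218 lower, and at 50 points or more 3565 were higher and 0 lower. In p53-null cells the means were 12.6% and 15.1%, 2.49 points apart (1.58 to 3.07 over the 20 chromosomes). There 14166 CpGs were higher and 2854 lower by at least 25 points, and 685 and 71 by at least 50 points. The genotype difference in RA-treated cells minus that in naive cells was -3.99 points, which equals the RA difference of p53-null cells minus that of WT cells. With each tile counting once, RA-treated and naive cells differed by 12.5 points in WT and 4.21 points in p53-null cells.

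Named CpGs higher after RA in WT cells included chromosome 15 (100964608 to 100964609), from 5% to 94%, chromosome 4 (136270010 to 136270011), from 5% to 93%, and chromosome 8 (47582443 to 47582444), from 0% to 86%. In p53-null cells they included chromosome 4 at 126893726 to 126893727, from 6% to 92%, and at 56869657 to 56869658, from 0% to 83%. The largest decreases after RA were -49 points in WT cells, on chromosome 17 (81540372 to 81540373), and -76 points in p53-null cells, on chromosome 7 (7478701 to 7478702). The latter CpG, also named above, was at 91% in naive and 15% in RA-treated p53-null cells. The CpG on chromosome 9 at 20039957, which led the naive increases, was at 94% and 23%. Both CpGs were named above for their high naive p53-null value. That value enters this comparison too, so their return here is no separate support.

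The tile table separates 5mC from 5hmC. It holds 2 sets of columns whose headings give the genotype and the modification but not the cell state, so they are described as the first and the second set. In the first set, with 246422 tiles, total methylation averaged 30.1% in WT and 38.8% in p53-null cells, 8.65 points apart. 5mC was 24.2% and 33.7%, a difference of 9.51 points, with p53-null cells the higher on 20 of 20 chromosomes (8.69 to 11.2 points). 5hmC, taken as total minus 5mC, was 5.96% in WT and 5.10% in p53-null cells, a difference of -0.859 points. It was lower in p53-null cells on 20 of 20 chromosomes, with differences from -1.29 to -0.522 points.

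In the second set, with 252014 tiles, total methylation averaged 42.5% in WT and 39.3% in p53-null cells, a difference of -3.18 points, and 5mC 40.5% and 36.4%, a difference of -4.07 points. Here 5hmC was the higher in p53-null cells, 2.84% against 1.96%, on 20 of 20 chromosomes (0.656 to 1.32 points). The estimate of 5hmC in single tiles was imprecise, since a difference between assays can fall below 0. In the first set 31.8% of tiles had 10 points or more of 5hmC in WT and 30.5% in p53-null cells, while 8.09% and 11.01% had -10 points or less. For the second set, 19.95% and 20.04% had 10 points or more, and 12.2% and 8.06% had -10 points or less. The genotypes thus differed more in the share of tiles at -10 points or less, values that no true 5hmC level can take, than in the share at 10 points or more.

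**Figure D3:**
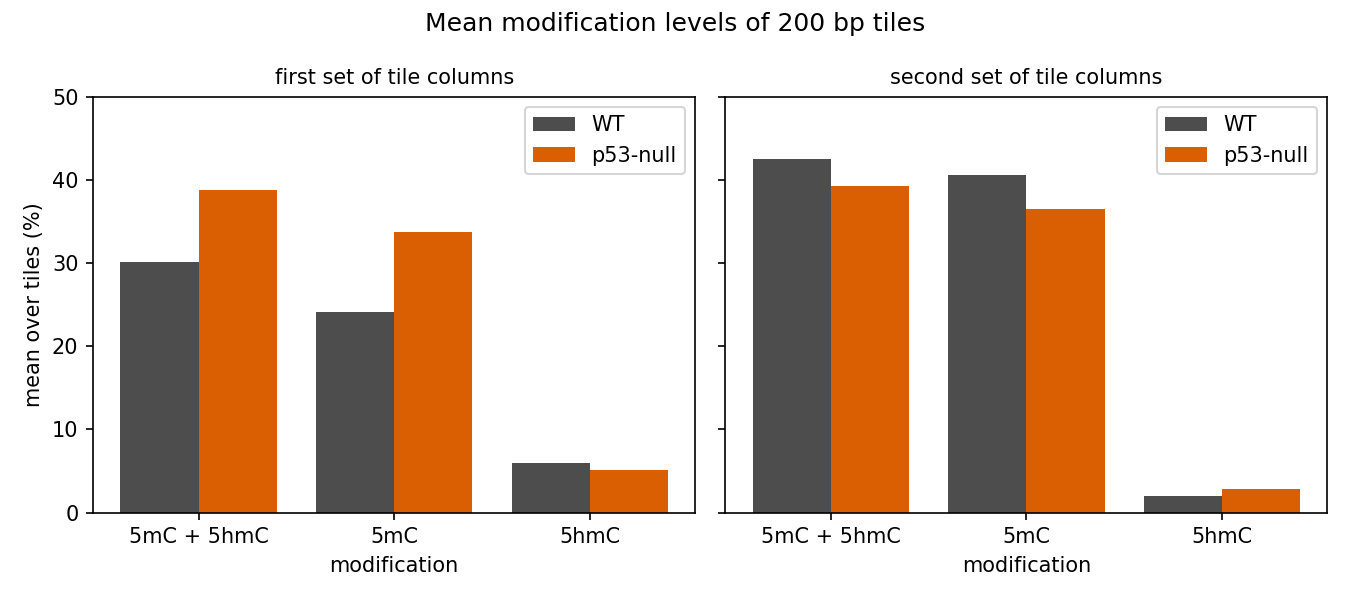
Mean level (percent of cytosines, vertical axis) of 5mC plus 5hmC, of 5mC and of 5hmC (horizontal axis) in WT and p53-null cells, for the first (left) and the second (right) set of tile columns; bars are means over tiles of the authors' pooled values, with no error bars. Total methylation is 30.1% against 38.8% on the left and 42.5% against 39.3% on the right.

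By the q-values of the authors' deposited table, with q under 0.05 and a difference of at least 10 points, 69182 tiles of the first set were higher and 1938 lower in p53-null cells in total methylation. For 5mC of that set the authors' deposited table gave 90213 higher and 14867 lower tiles. In the second set the counts from the authors' deposited table were 1212 higher and 9201 lower for total methylation, and 7082 higher and 30926 lower for 5mC. At q under 0.01 and 25 points, the authors' deposited table gave 16056 higher and 256 lower tiles in the first set and 120 and 1242 in the second, for total methylation. Whether the spread between libraries entered these q-values is not given in the sources used here.

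The share of tiles called differed with the level in the other set, and not in the same way in both. Of first-set tiles at 40% to 60% in the second set, the authors' deposited table called 43.2% higher and 0.758% lower in total methylation. Under 5% it called 0.152% higher and 0.0299% lower, and above 80% it called 28.1% higher and 0.924% lower. Of second-set tiles at 40% to 60% in the first set, the authors' deposited table called 0.472% higher and 4.81% lower. The share it called lower was highest, 5.79%, at 5% to 20% in the first set, and was 0.504% under 5% and 1.92% above 80%. Over the 214665 tiles with values in both sets, 2943 were called higher in the first and lower in the second set in the authors' deposited table, where independent lists of these sizes would share 2375. In the authors' deposited table, 170 tiles were lower in both sets against 53.7 for independent lists, 530 were higher in both against 304.8, and 12 were lower in the first and higher in the second against 6.89. All 4 pairs exceeded independent lists, which are drawn from all tiles although few tiles under 5% were called, so these values are not those expected without a shared change.

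**Figure D4:**
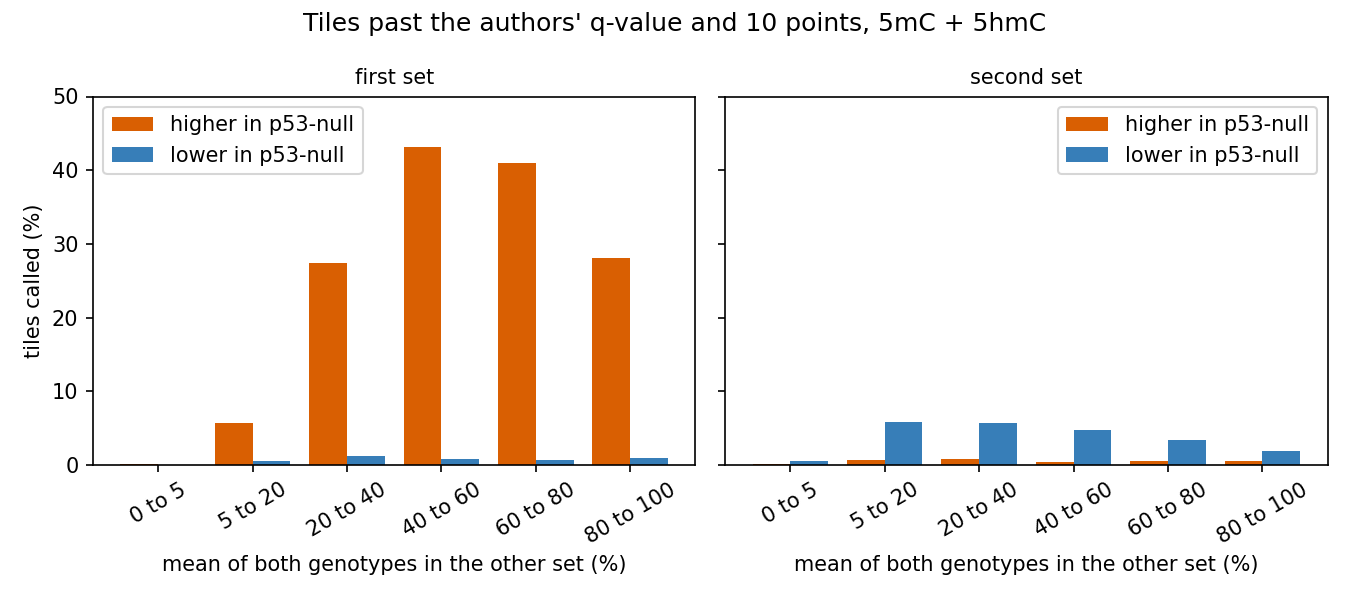
Share of 200 bp tiles (percent, vertical axis) called higher or lower in p53-null cells in total methylation by the q-value of the authors' deposited table and a difference of at least 10 points. Tiles are grouped by their mean level in the other set (horizontal axis), and in the class from 40% to 60% the first set (left) has 43.2% called higher and the second set (right) 4.81% called lower.

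The named tiles of the first set with the largest increases in total methylation, all called in the authors' deposited table, were higher by 77.1 to 87.0 points. They included chromosome 6 (40914401 to 40914600), at 100% in p53-null cells and 87.0 points above WT. Others were chromosome 1 (87789201 to 87789400), 8.33% in WT and 93.8% in p53-null cells, chromosome 7 (58691801 to 58692000), 7.69% and 90.5%, and chromosome X (30774401 to 30774600), 9.09% and 91.7%. The decreases ranged from -69.2 to -56.9 points in the authors' deposited table. They included chromosome 16 (91641001 to 91641200), 76.9% and 7.69%, and chromosome 11 (89267001 to 89267200), 69.7% and 6.45%. Levels such as 8.33%, 7.69% and 9.09% are values that small read counts can give. The largest changes of single tiles, in either set, may therefore rest on few reads, although depth is not given. For 5mC, 33 tiles of the first set called in the authors' deposited table were tied at an increase from 0% to 100%, among them chromosome 10 (27434201 to 27434400, q = 9.12e-10 in the authors' deposited table).

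In the second set the largest decreases in total methylation in the authors' deposited table were -72.7 points on chromosome 10 (121584201 to 121584400), from 90.9% in WT to 18.2%, and -71.1 points on chromosome 18 (71160601 to 71160800), from 100% to 28.9%. The largest increases were on chromosome 3 (44308801 to 44309000), from 11.1% to 72.4% (q = 0.0019 in the authors' deposited table), and on chromosome 2 (75047001 to 75047200), from 21.7% to 82.1% (q = 0.0011 in the authors' deposited table). The difference between the genotypes was spread along the genome. In windows of 1000000 bp with at least 20 tiles, p53-null cells had the higher mean total methylation in 2530 of 2531 windows of the first set, with a median of 8.87 points. They had the lower mean in the second set in 2446 of 2520 windows, with a median of -3.24 points.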

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

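The tests of conversion, of single chromosomes, of pooled lines and of oxidation were chosen after the results were seen. The differences between states and between sets given here were not tested, since no values per library were used.

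The genotype difference in total methylation had opposite signs in naive and RA-treated cells, 2.82 and -1.17 points, and the latter minus the former was -3.99 points. Unconverted cytosines in the naive p53-null libraries would add most where nothing is methylated. The 145310 CpGs at 0 in both RA columns differed by 0.0204 points in naive cells, which argues against incomplete conversion as the cause. A few chromosomes do not account for it either, since 20 of 20 had the higher naive value in p53-null cells. Different cell lines, clones, sexes of lines or batches pooled in each group cannot be told apart from genotype, because each group has 1 column of values; loss of p53 may act differently in the 2 states, and that stays open as a hypothesis.

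Over the 214665 tiles with values in both sets, the genotype difference in total methylation was 8.45 points in the first and -3.105 points in the second set, the latter minus the former being -11.6 points. The genotype difference in 5hmC over these tiles was -0.833 points in the first and 0.850 points in the second set, 1.68 points apart and, as a mean, opposite in sign to that of 5mC in each set. By level this did not hold throughout: in first-set tiles under 5%, at 5% to 20% and at 20% to 40% in the second set, 5hmC was the higher in p53-null cells, by 0.0796, 0.479 and 0.109 points, as 5mC was. Less complete oxidation in the libraries with the lower 5hmC would leave 5hmC read as 5mC. In first-set tiles at 60% to 80% in the second set, 5hmC in p53-null cells was 0.781 of that in WT cells, and in tiles at 5% to 20% and at 20% to 40% it was 1.29 and 1.02 of it. Incomplete oxidation predicts a constant ratio only if 5hmC is otherwise alike, and total methylation of these tiles also differed, so oxidation and genotype cannot be told apart. Oxidation does not enter total methylation, which differed by 8.45 points in the first set of these tiles, where 5mC differed by 9.28 points.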

How the results depend on the processing

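The alternatives other than autosomes only and the stricter call were chosen after seeing the data. No paired analysis was possible because the tables hold 1 pooled column per group, with no replicate numbers. Coverage minima, other models, all groups in 1 fit and leaving out replicates were not run for the same reason. The tile table was not put in place of the CpG table for a labelled group, because its headings name no cell state. Hence nothing here measures how far single libraries or depth limit the results. Over 19 results, 57 alternatives were run. Counts of calls in 1 direction and shares of CpGs have no sign, so only the mean differences could reverse, and 0 did. All alternatives reuse the same pooled values. Of the 57, 26 left the value alike to the second decimal, or within 1.5 times for a count, and 31 moved it.

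With each tile counting once, the mean differences grew because CpG-dense tiles weigh less: 5.98 points (naive genotype), -2.33 (RA genotype), 12.5 (WT, RA minus naive), 4.21 (p53-null, RA minus naive) and -8.31 (difference between states). Over CpGs above 0 in any total column, they were 4.22, -1.75, 9.69, 3.72 and -5.97 points in the same order. On autosomes only, the last 3 were 6.50, 2.5005 and -4.00 points. The shares of CpGs between 20% and 80% on autosomes were 18.2% and 19.5% in naive WT and p53-null cells and 23.1% in RA-treated WT cells. In the second set 5hmC differed there by 0.875 points. In tiles of both sets, 5hmC differed by -0.833 points in the first and 0.850 in the second set, and in tiles over 20% in the other set by -1.20 and 1.27 points. At 25 points and q under 0.01 in the authors' deposited table, total methylation gave 16056 higher and 256 lower tiles in the first and 120 and 1242 in the second set. The 5mC counts in the authors' deposited table were then 42144 and 5014, and 1504 and 8318. At q under 0.05 and any size, the first set had 4172 lower tiles for total methylation and 22347 for 5mC in the authors' deposited table.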

Other observations

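The tests of the number of methylated CpGs in the window, of a segment reaching to it, of tiles with 1 and 2 CpGs and of the unnamed columns were chosen after the result was seen. The tests of neighbouring CpGs, of tiles with 5 or more CpGs and of neighbouring tiles were written before their results.

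CpGs lower in p53-null cells in both states were clustered on chromosome 11, the chromosome that carries the p53 gene. Over the genome, 62 CpGs were lower by at least 25 points in naive and in RA-treated p53-null cells, while 187 were higher by as much in both. Of the 62, 13 lay on chromosome 11. The window from 85000001 to 90000000 held 7, the other 6 lay beyond it, and no other of the 539 windows of 5 Mb held more than 2. These 7 CpGs were at 37% to 79% in the WT columns and at 0% to 20% in the p53-null columns. Their mean difference was -44 points in naive and -58.6 points in RA-treated cells. Examples are 88327784 to 88327785, from 69% to 8% in naive and from 63% to 7% in RA-treated cells, and 89508768 to 89508769, from 53% to 5% and from 63% to 0%. By the q-values of the authors' deposited table, 12 of 552 tiles in this window were lower in both sets, 2.17%, against 170 of 214665 over the genome. In the authors' deposited table that share was the highest of the 515 windows with at least 100 tiles, but close to the 1.92% (3 of 156 tiles) on chromosome 3 from 70000001 to 75000000.

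A larger number of methylated CpGs does not account for the cluster. Of CpGs at 25% or more in both WT columns, 7 of 126 in the window and 55 of 55467 elsewhere were lower in both states, 56.0 times the share (Fisher's exact test, two-sided, p = 1.15e-10, with the window chosen for its count and CpGs not independent). The window is many megabases away from the p53 gene, as general knowledge of the mouse genome has it. In the 5 Mb before it, from 80000001 to 85000000, 0 of 134 such CpGs were lower in both states, against 5.56% in the window. With 3 more than observed the share would be 2.24%, an approximate upper limit that takes CpGs as independent. Those 134 CpGs are too few to exclude a strain segment with variants along its length that reaches from the disrupted gene to the window. On chromosome 11 from 1 to 85000000, 0 of 2012 such CpGs were lower in both states, where the same approximate limit is 0.149%. This goes against variants spread over all of that stretch. It does not decide on a segment from the gene to the window, which need not cover all of that stretch. How many of the 2012 lie between the gene and the window is unknown, since the position of the gene on mm9 was not used. A base change that removes single CpGs in the window is another candidate explanation and predicts that nearby CpGs keep their methylation. The 7 other CpGs within 1000 bp that were at 20% or more in naive WT cells lie near 3 of the sites. They differed on average by -4.14 points in naive and -13.7 points in RA-treated cells, against -44 and -58.6 points for the sites. The mean covers unlike values: the CpG near 87633718 differed by 1 and -11 points, the 2 near 88327784 by a mean of 13 and -1, and the 4 near 89977164 by a mean of -14 and -20.8. A local loss of methylation therefore stays open, above all at 89977164, and no sequence was used that would show a base change.

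A stretch of chromosome X stood out in the other direction. From 24000001 to 33000000, total methylation of first-set tiles averaged 47.9% in WT and 68.3% in p53-null cells, against 32.3% and 41.7% over the rest of the chromosome. In the second set the stretch averaged 46.2% in WT and 48.8% in p53-null cells, while the rest of the chromosome averaged 40.1% and 37.5%. The 5 windows of 1000000 bp with the largest first-set difference included 3 in this stretch, with 25.02 points from 26000001 to 27000000, 23.95 from 24000001 to 25000000 and 23.6 from 28000001 to 29000000. The other 2 were on chromosome 7, with 23.6 points from 8000001 to 9000000 and 20.4 from 10000001 to 11000000. The first-set contrast of the stretch with the rest of the chromosome uses the same values and is no independent support. The stretch also holds windows among the 5 of largest second-set difference, with 4.78 points from 28000001 to 29000000 and 4.63 from 32000001 to 33000000. The second-set contrast is therefore not taken as independent support either. The only first-set window with the lower mean in p53-null cells was on chromosome X, from 141000001 to 142000000, at -0.247 points. The labels give no sex for the mESC lines. Tiles of chromosome Y had values in both genotypes at 22 positions of the first and 17 of the second set.

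The smaller difference of CpG-dense tiles was set against their lower methylation. Among tiles at 40% to 80% in RA-treated cells, tiles with 1 measured CpG differed by 12.1 points in naive cells (SD over chromosomes 0.522, 36200 tiles). Those with 2 differed by 10.8 points (SD 0.496, 8208 tiles), those with 3 to 4 by 10.2 points (SD 1.40, 2756 tiles) and those with 5 or more by 8.47 points (SD 2.48, 239 tiles), the last being 0.699 of the first. With tiles of 1 and 2 CpGs matched in classes of 5 points of RA level, those with 1 CpG differed by 1.32 points more (SD over chromosomes 0.377), on 20 of 20 chromosomes. The matching did not make the naive levels alike, however: WT averaged 41.2%, 37.1%, 33.8% and 31.0% in the 4 classes of matched tiles. As a share of that level the difference was 29.4%, 29.2%, 30.2% and 27.3% (SD over chromosomes 1.42, 1.56, 3.29 and 8.48). The difference is not a constant share of the WT level in general, however. Over single CpGs grouped by RA level, it was 11.1 points at a naive WT mean of 30.0% and 11.9 points at 47.6%. The alike shares therefore do not show that lower methylation accounts for the whole pattern. Its part cannot be told apart from that of density.

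The genotype difference was alike in close tiles. In the first set it correlated over tiles at r = 0.450 between adjacent tiles, 0.0772 from 2 to 10 kb and 0.0258 from 10 to 100 kb. After subtracting the mean of the level class, the values were 0.259, 0.0355 and 0.0116. Between adjacent tiles of the second set r was 0.281 before and 0.252 after the subtraction, so the level classes left most of the similarity of adjacent tiles there. Tiles are not independent replicates. At 10 to 100 kb, the distance chosen for the test, there was little correlation to explain before the subtraction, so that test decides nothing.

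The first set of tile columns resembled the naive cells more than the RA-treated cells. Over 95601 tiles its total methylation correlated with the naive CpG column at r = 0.953 in WT and 0.966 in p53-null cells, and with the RA column at 0.877 and 0.894, so that the smallest excess was 0.0719. For the second set the order was the opposite, with 0.965 and 0.968 for the RA columns and 0.867 and 0.893 for the naive columns. Only mESC were profiled with oxRRBS, so the 5mC values of both sets are not from liver. If the sets hold naive and RA-treated cells, they rest on the same libraries as the single CpGs. The tile results are then no separate support for those of the CpGs. Whether the undefined CpG columns estimate 5mC stays open. They correlated with the 5mC tiles of the same genotype more than with the 5hmC tiles, by at least 0.587. They were above total methylation at 0 CpGs. In this they were unlike tile 5mC, which exceeded the total by at least 10 points in 8.06% to 12.2% of tiles, by set and genotype. Total methylation itself also correlated more with 5mC than with 5hmC tiles (0.865 against 0.592 for naive WT and the first set). The undefined column followed 5mC more closely than total methylation did, at 0.894 for naive WT and the first set. It followed 5hmC less closely, at 0.308. Both orders held in each genotype and state, with naive cells set against the first set and RA-treated cells against the second. This goes with an estimate of 5mC, but the levels differed. Over the same 95601 tiles the undefined column averaged 55.8% of total methylation in naive WT and 76.1% in RA-treated WT cells, below the 67.4% and 86.9% that 5mC made up of the total in the first and the second set.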
